A study of Mus musculus with 32 samples.

How the data were processed

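Single-cell RNA was measured in CD31-positive, CD45-negative endothelial cells and in CD45-positive immune cells from macrodissected liver metastases of mice. A time after transfer of anti-tumour T cells is given for every group but the endothelial control (Ctrl). Each endothelial group came from 4 wells with their hashtag libraries, and each immune group from 1 library with its hashtag library. Chemistry was a 3′ kit per the labels, except in the knock-in series (iECKI), which used a 5′ kit. Per the submitters' processing notes, the authors aligned reads to mm10 with Cell Ranger and analysed cells with Seurat, with no versions. The headers of the matrices give cellranger 7.0.0 for WT and iECKO and 9.0.1 for iECKI, and no version for the endothelial matrices. The deposited matrices hold counts, that is, whole-number UMI counts per gene and cell, with hashtag counts beside them. Whether the authors' aggregation equalised depth is not given in the sources used here. Deposited notes pair 6 hashtags with 6 mice, and each barcode suffix was given the hashtag with the highest median count. The suffixes gave 5 mice in Ctrl, 6 in Early, 4 in Late, 6 in WT, 6 in iECKO and 10 in iECKI, and the mouse was the replicate throughout.

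Cells were kept with at least 500 UMIs, at least 300 genes and under 15% mitochondrial counts, which left 6933 of 7068 Ctrl cells, 2442 of 2477 Early, 765 of 806 Late, 7478 of 8028 WT, 7359 of 8039 iECKO and 44902 of 45711 iECKI cells. Cells per mouse as deposited ranged from 280 to 4245 in Ctrl, 54 to 894 in Early, 91 to 449 in Late, 1010 to 1491 in WT and 1120 to 1650 in iECKO. The median UMIs per cell were 7094.5, 6424, 7005, 16502 and 13720 in that order, and 3639 in iECKI. Scrublet, as called through scanpy 1.11.5, marked 0 to 6 cells per endothelial or WT and iECKO matrix with its automatic threshold, so the highest-scoring cells were removed instead: 452 Ctrl, 158 Early, 65 Late, 512 WT and 514 iECKO cells. In iECKI the 592 cells past the automatic threshold were removed.

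Cells were clustered with scanpy (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8 with igraph 0.11.9) in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A cluster took the name of a marker list, with "-like" added in the text, when at least 3 of its markers were higher by at least 0.5 on the log2 scale, its score was at least 0.5 and its top genes did not favour a rival list. Clusters that met no such rule kept their numbers. Endothelial-like cells are all endothelial clusters but an immune-like and an erythroid or platelet cluster. They numbered 6455 in Ctrl, 2258 in Early and 700 in Late.

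UMIs were summed per mouse and class for mice with at least 10 cells. Genes passed filterByExpr and were tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3, limma 3.58.1) with TMM factors, the 3 endothelial groups in 1 fit, and Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 ratio is its size over the square root of the F statistic. CPM are means and SD over mice. Gene lists fixed before the data were examined were tested with camera, both with its preset and with an estimated correlation, and all list adjusted p are from camera. Shares of classes were compared between mice with two-sided exact permutation tests, whose smallest p is 0.00216 for 6 against 5 mice or 6 against 6, 0.00794 for 4 against 5 and 0.00476 for 4 against 6. For a gene with no UMI in a group, a floor of 3 counts over the group gives the bound, and 1 to 3 UMIs give a ratio with a 95% counting interval. Identifiers of 32158 of 32285 genes matched the reference annotation.

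The genes named were, per comparison and class, the 12 with the largest log2 ratio up and the 12 down (5 and 5 in smaller classes) among genes past the threshold with a mean of at least 10 CPM, of which some are not reported here. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, gene models with Gm or Rik names, Xist, Tsix and Y-linked genes were left out. So were markers of hepatocyte, erythroid, stellate, epithelial and melanocytic cells, and markers of immune cells in the endothelial data alone. Other X-linked genes stayed in. Lpl and members of the lists with the largest ratios were given as well. Other genes named were chosen after their values were seen.

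Alternatives fixed before the data were examined covered the cell filter, doublets, resolution, DESeq2 1.42.0, limma on the mean of per-cell CPM, no filter on low counts, stricter hashtag calls, a block on mouse number and each mouse left out. Alternatives chosen after seeing the data were total UMIs without TMM factors, only the 2 groups compared in the fit, subtraction of the same mouse's other immune cells, iECKO mice 1 and 6 left out together, and clusters rebuilt without the called genes, which give the shares in the report. Other choices made after the data were examined, before the tests, were the authors' assignment of cells to mice in place of a hashtag rule of 70%, the number of doublets removed and the rules for naming clusters. Which classes to follow through the alternatives was chosen after the counts were seen. Mouse numbers were checked as pairs: own pairs had correlations across genes from -0.126 to 0.0445 between Early and Ctrl, 0.0704 to 0.282 between Late and Ctrl, -0.136 to 0.0453 between Late and Early and -0.0522 to 0.294 between iECKO and WT. In that order 0 of 5, 2 of 4, 0 of 4 and 3 of 6 matched their own number best. Mice were not paired, and the mouse number entered as a block in an alternative.

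The tests were checked on simulated counts, drawn from negative binomial distributions with the means, library sizes and dispersions of the mice, in which 200 genes were changed. Among all endothelial-like cells in Early against Ctrl, 25.4% of genes changed 1.5-fold were called, 68.7% at 2-fold and 98.5% at 4-fold, with 0 called in the wrong direction and 7 unchanged genes called. In the T cell clusters these shares were 53.7%, 71.6% and 97.0%, with 8 unchanged genes called. The mice of the iECKI matrix, for which the labels name an LSL-WT and a knock-in library, were left out of comparisons because which mouse has which genotype is not given in the sources used here. An earlier round of exploratory fits preceded the final settings.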

Results

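The data are single-cell RNA counts from mice carrying liver metastases. A time after transfer of anti-tumour T cells is given for every group but the endothelial control, for which no transfer is stated. CD31-positive, CD45-negative endothelial cells were sorted from dissected metastatic nodules of control mice (Ctrl, 5 mice), of mice 2 days after T cell transfer (Early, 6 mice) and of mice 4 days after it (Late, 4 mice). CD45-positive immune cells were taken 2 days after transfer from wild-type mice (WT, 6 mice) and from mice in which lipoprotein lipase (Lpl) had been deleted inducibly in endothelium (iECKO, 6 mice). A further immune matrix, named iECKI, holds 10 mice in 2 hashtag sets of 4 and 6 tags. The labels name a wild-type (LSL-WT) and a knock-in library for it, and which mice have which genotype is not given in the sources used here, so those mice entered no comparison. The Ctrl matrix held 7068 cells, Early 2477, Late 806, WT 8028, iECKO 8039 and iECKI 45711. UMIs per mouse ranged from 2969929 to 36334761 in Ctrl, 372800 to 6707302 in Early, 955052 to 3732987 in Late, 17119061 to 30815686 in WT, 15485704 to 26766582 in iECKO and 16094826 to 27536013 in iECKI. All mice of a group shared a library set, so library and group cannot be separated in any comparison. Values are TMM-scaled CPM, that is UMI counts scaled to a common library total, as mean ± SD over mice, and log2 ratios with their standard error (SE). Counting intervals and floors cover counting error alone.

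The first comparison asked how the endothelium of metastatic nodules differed 2 days after T cell transfer. All 31 interferon-stimulated, 16 class I and 7 class II genes measured were higher in Early than in Ctrl, and all 16 proliferation genes were lower (camera adjusted p of 0.0278 to 0.0368 with an estimated correlation). Cd274, which encodes the inhibitory ligand PD-L1, stood at 303 ± 164 CPM in 6 Early mice and 21.4 ± 14.3 CPM in 5 Ctrl mice, a log2 ratio of 3.90 ± 0.44 (edgeR adjusted p = 1.23e-05). Mki67, a marker of cycling cells, stood at 4.62 ± 3.87 CPM in Early and 71.6 ± 17.9 CPM in Ctrl, a log2 ratio of -3.73 ± 0.35 (edgeR adjusted p = 4.04e-06). Each Early mouse lay above each Ctrl mouse for Cd274 and below each for Mki67. Of 11956 genes tested in endothelial-like cells, 1031 rose and 1156 fell.

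All 31 measured interferon-stimulated genes rose, also when adjusted over the list alone, with a median log2 ratio of 1.96 (camera adjusted p = 4.55e-34, adjusted p = 0.0278 with an estimated correlation). The transcription factor Irf1 rose by 1.63 ± 0.17 on the log2 scale. The guanylate-binding proteins Gbp5 and Gbp2, which act in cell-autonomous defence, rose by 3.26 ± 0.46 and 3.14 ± 0.45, Gbp10 by 5.80 ± 0.59 and Apol10b by 3.21 ± 0.45. Ido1, which degrades tryptophan, had a log2 ratio of 6.53 ± 1.14 with 25.5 ± 34.2 CPM in Early against 0.566 ± 0.517 CPM in Ctrl. All 16 genes of MHC class I presentation rose (16 adjusted over the list alone), with a median of 1.62 (adjusted p = 0.0278 with an estimated correlation). The peptide transporter Tap1 rose by 2.13 ± 0.24 and the light chain B2m by 1.13 ± 0.14.

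MHC class II genes, better known from antigen-presenting leukocytes, had the largest median ratio of the lists in this comparison. All 7 rose (7 adjusted over the list alone), with a median of 3.88 (camera adjusted p = 7.62e-10, adjusted p = 0.0368 with an estimated correlation). H2-Aa went from 10.4 ± 14.9 to 186 ± 65.9 CPM, a log2 ratio of 4.59 ± 0.65, and the invariant chain Cd74 from 41.2 ± 66.0 to 444 ± 180 CPM. H2-Eb1 rose by 4.54 ± 0.69, H2-Ab1 by 3.88 ± 0.58, the peptide-exchange subunit H2-DMb1 by 3.47 ± 0.63 and Ciita, the master regulator of class II transcription, by 4.47 ± 0.49. Summed CD8 T cell markers in these cells were 0.113 CPM in Early and 0.249 CPM in Ctrl, and summed neutrophil markers 2.10 and 2.07 CPM. Kupffer cell markers summed to 6.996 ± 7.98 CPM in Early and 1.59 ± 0.805 CPM in Ctrl, and monocyte markers to 285 ± 104 and 146 ± 71.8 CPM.

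Of 5 measured chemokines that recruit T cells, 4 rose (4 adjusted over the list alone), with a median of 1.62 (camera adjusted p = 0.0045, adjusted p = 0.0368 with an estimated correlation). Cxcl9 rose by 2.49 ± 0.52 to 2594 ± 1260 CPM, Cxcl10 by 1.90 ± 0.41, Cx3cl1 by 1.62 ± 0.49 and Cxcl16 by 0.63 ± 0.14. The adhesion list was not called (camera adjusted p = 0.199): 2 of 9 members rose (2 adjusted over the list alone). Vcam1, which binds leukocyte integrins, rose by 1.24 ± 0.18, while Icam1 had a log2 ratio of 0.19 ± 0.16 and Sele of -0.68 ± 0.27, neither past the threshold. In the cell death list 8 of 14 genes rose and 2 fell (8 and 3 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.00908, adjusted p = 0.0368 with an estimated correlation). The nucleic acid sensor Zbp1 led it with 2.62 ± 0.37, and the death receptor Fas rose by 0.96 ± 0.13.

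All 16 proliferation genes fell (16 adjusted over the list alone), with a median of -2.13 (camera adjusted p = 2.28e-14, adjusted p = 0.0368 with an estimated correlation). Top2a, which untangles replicated DNA, fell from 133 ± 55.5 to 11.1 ± 7.13 CPM. Besides Mki67 and Top2a, given above, the named genes that fell furthest were Hmmr at -4.08 ± 0.40, Hist1h2ap at -4.02 ± 0.62, Ube2c at -4.00 ± 0.42, Hist1h1b at -3.86 ± 0.73 and Cenpf at -3.57 ± 0.37. Next came Cdca8 at -3.55 ± 0.33, Anln at -3.42 ± 0.32, Hist1h2ae at -3.36 ± 0.57, Prc1 at -3.34 ± 0.40 and Kif11 at -3.23 ± 0.43. The cluster led by Top2a and Mki67 held 8.10 ± 2.72% of endothelial-like cells in Ctrl and 1.23 ± 0.519% in Early (two-sided exact permutation test, adjusted p = 0.0195). That clustering used the changed genes themselves. Among 16 angiogenic tip cell genes 6 fell and 1 rose (6 and 1 adjusted over the list alone). Apln, a peptide of sprouting vessels, had a log2 ratio of -1.83 ± 0.43 and Esm1 of -1.87 ± 0.58, and the list as a whole was not called (camera adjusted p = 0.0808).

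Of 8 genes around Wnt2 and Rspo3, angiocrine signals of the pericentral liver, 3 rose, and 6 adjusted over the list alone, with a median of 0.68 (camera adjusted p = 0.000931, adjusted p = 0.0278 with an estimated correlation). Wnt9b rose by 1.74 ± 0.44. Of 14 sinusoidal genes 6 rose and 1 fell (9 and 1 adjusted over the list alone). Ehd3 had a log2 ratio of 0.94 ± 0.30 and Lyve1 of -0.82 ± 0.24 (camera adjusted p = 0.000158, adjusted p = 0.332 with an estimated correlation). The periportal and arterial list had 2 of 12 genes higher (2 adjusted over the list alone), Ly6a at 1.98 ± 0.21 and Gja4 at 1.37 ± 0.19 (camera adjusted p = 0.0268, adjusted p = 0.332 with an estimated correlation). In the matrix list 4 of 10 genes fell, 6 adjusted over the list alone (camera adjusted p = 0.0095, adjusted p = 0.209 with an estimated correlation). Summed stellate or fibroblast markers went from 70.04 ± 42.7 to 30.8 ± 20.8 CPM. Melanocytic markers went from 129 ± 144 to 20.4 ± 10.2 CPM and epithelial markers from 6.72 ± 5.37 to 60.6 ± 79.4 CPM. Of 15 immediate-early genes, which cell dissociation can induce, 4 fell (4 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.332 with an estimated correlation). No call was made for the hypoxia list (3 up and 5 down of 13, also adjusted over the list alone, camera adjusted p = 0.432), the vein list (2 up of 8, also adjusted over the list alone, 0.0912) or the lymphatic list (0 of 5, also adjusted over the list alone, 0.299).

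Genes of lipid uptake were not called as a list (1 of 11 up and 2 down, 2 and 3 adjusted over the list alone, camera adjusted p = 0.622). Cd36, a fatty acid transporter, rose by 0.73 ± 0.14 and the lipase inhibitor Angptl4 fell by 1.99 on the log2 scale. Lpl itself (ENSMUSG00000015568, mm10 chromosome 8, 68880491 to 68907448) stood at 33.9 ± 56.5 CPM in Early and 5.90 ± 5.79 CPM in Ctrl (log2 ratio 2.52 ± 0.92, edgeR adjusted p = 0.066). Leaving out Ctrl mouse 4 lowered the count of changed genes from 2187 to 1403, and limma on the mean of per-cell CPM called 954. The longest 10% of genes exceeded the shortest 10% by a median log2 ratio of 0.37. The share of called genes that were higher was 47.1% with TMM factors and 36.6% with total UMIs alone.

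**Figure D1:**
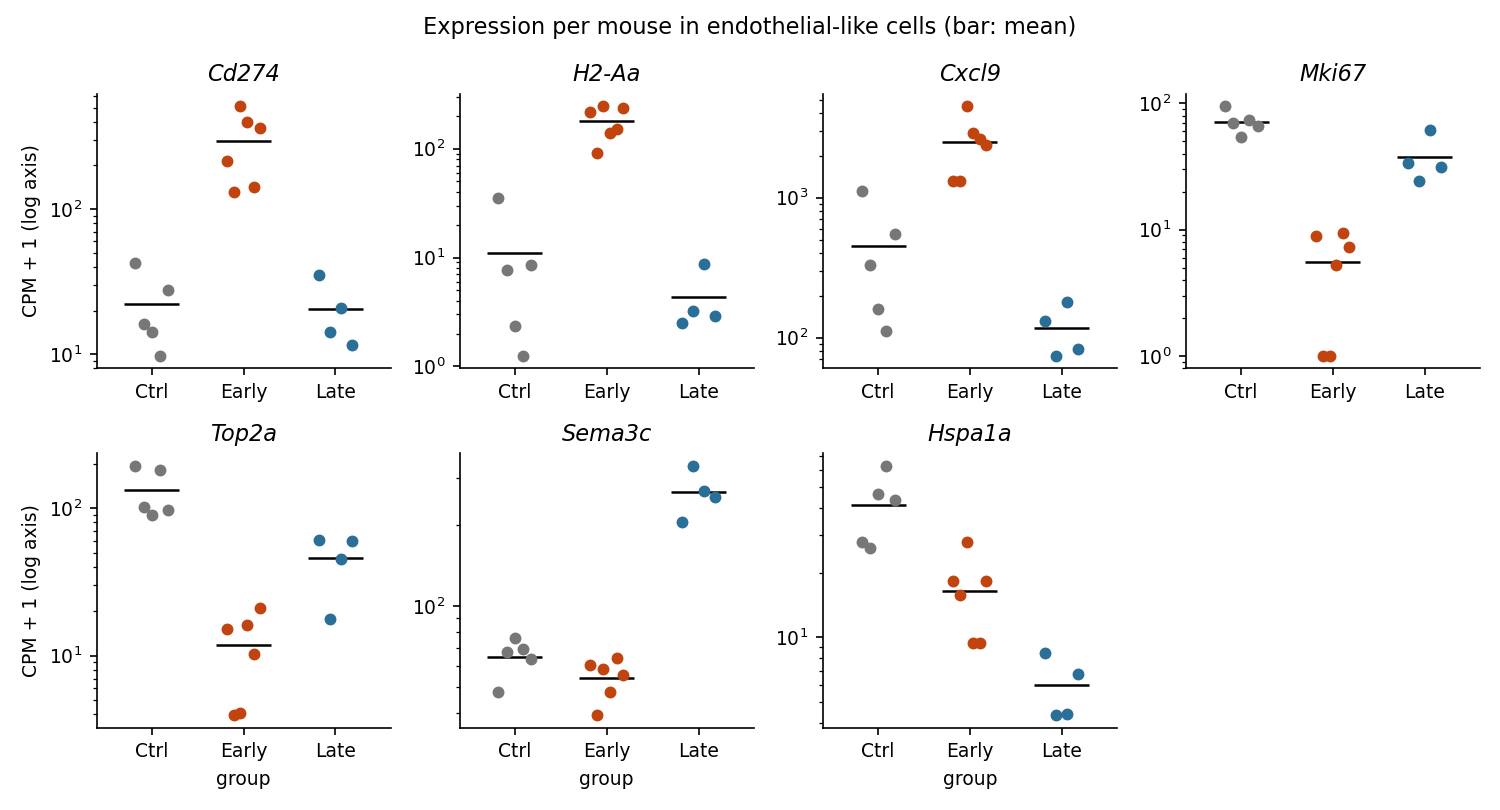
CPM plus 1 (log axis, not TMM-scaled) of 7 genes in endothelial-like cells, 1 point per mouse (5 Ctrl, 6 Early, 4 Late), the bar at the mean. By their means Cd274, H2-Aa and Cxcl9 are highest in Early, Mki67 and Top2a are lowest in Early, Sema3c is highest in Late, and Hspa1a is lowest in Late. Cxcl9 is also lower in Late than in Ctrl.

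At 4 days after transfer the endothelium was compared with Ctrl again, to ask what differed at the later time. Sema3c, which encodes a secreted semaphorin guidance cue, and Lrp1b, a giant endocytic receptor, were higher in Late, and the heat shock gene Hspa1a was lower. Sema3c (ENSMUSG00000028780, mm10 chromosome 5, 17574281 to 17730268) stood at 257 ± 46.5 CPM in 4 Late mice and 63.9 ± 8.71 CPM in 5 Ctrl mice, a log2 ratio of 2.00 ± 0.14 (edgeR adjusted p = 6.4e-07), with each Late mouse above each Ctrl mouse. Hspa1a stood at 4.89 ± 2.09 CPM in Late and 40.5 ± 15.3 CPM in Ctrl (log2 ratio -3.25 ± 0.44, edgeR adjusted p = 0.000485). In all, 600 genes rose and 824 fell, and the median log2 ratio was 0.11 in the longest 10% of genes and -0.17 in the shortest.

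Of 14 sinusoidal genes 6 rose, and 11 adjusted over the list alone, with a median of 0.95 (camera adjusted p = 2.5e-07, adjusted p = 0.307 with an estimated correlation). Ehd3 rose by 1.49 ± 0.32, the Fc receptor Fcgr2b by 1.30 ± 0.31, Bmp2, a regulator of hepatic iron handling, by 1.00 ± 0.31 and the sinusoidal transcription factor Gata4 by 0.85 ± 0.23. In the Wnt2 and Rspo3 list 2 of 8 genes rose, 3 adjusted over the list alone, with a median of 0.86 (camera adjusted p = 0.000152, adjusted p = 0.0209 with an estimated correlation). Wnt2 went from 84.9 ± 59.4 to 225 ± 49.9 CPM and Wnt9b from 37.1 ± 36.7 to 131 ± 23.01 CPM. Other genes among those that rose furthest were Grik1 at 2.29 ± 0.23, Naaladl2 at 2.21 ± 0.28, the noncoding RNA Bc1 at 2.09 ± 0.31 and Gpr155 at 1.87 ± 0.40. They were followed by Lrp1b at 1.86 ± 0.16, Tpbgl at 1.69 ± 0.28, Tiam1, an activator of Rac, at 1.498 ± 0.25 and Dnm3os at 1.42 ± 0.30.

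Of 15 immediate-early genes 13 fell, and 14 adjusted over the list alone, with a median of -1.38 (camera adjusted p = 2.65e-12, adjusted p = 0.0209 with an estimated correlation). Atf3 had a log2 ratio of -2.42 ± 0.35, Fos of -2.05 ± 0.33, Jun of -1.70 ± 0.23 and Egr1 of -1.48 ± 0.39. In the lymphatic list 4 of 5 genes fell (4 adjusted over the list alone), with a median of -4.95 (camera adjusted p = 0.000865, adjusted p = 0.11 with an estimated correlation). Mmrn1 had 3 UMIs in all Late mice together, a ratio of Ctrl to Late of 77.1 with a counting interval from 26.4 to 374. The guidance glycoprotein Reln had a log2 ratio of -4.95 ± 0.64, and Prox1, the master regulator of lymphatic identity, of -2.57 ± 0.53. Ccl21a, whose symbol several identifiers share and which is given here for ENSMUSG00000094686, had a log2 ratio of -6.34 ± 1.15. No Late cell fell in the lymphatic-like class (0 of 700 cells, which allows a share of up to 0.429%).

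Interferon-stimulated genes were lower than in Ctrl for 10 of 31, and for 21 adjusted over the list alone, with a median of -0.69 (camera adjusted p = 3.1e-09, adjusted p = 0.307 with an estimated correlation). Cxcl10 went from 186 ± 126 to 33.2 ± 17.9 CPM and Cxcl9 from 464 ± 436 to 113 ± 46.6 CPM, the 2 chemokines of 5 that fell (2 adjusted over the list alone, camera adjusted p = 0.16). Class II genes had a median of -0.78 with 0 of 7 called (0 adjusted over the list alone, camera adjusted p = 0.461), and class I genes a median of 0.10 with 2 of 16 up, H2-K1 among them at 0.73 ± 0.19 (6 up and 3 down adjusted over the list alone, camera adjusted p = 0.172). Proliferation genes fell for 4 of 16, 11 adjusted over the list alone (median -0.79, camera adjusted p = 0.000692, adjusted p = 0.376 with an estimated correlation). Top2a had a log2 ratio of -1.60 ± 0.38. Matrix genes fell for 3 of 10, 5 adjusted over the list alone (camera adjusted p = 0.00851, adjusted p = 0.307 with an estimated correlation), with fibronectin, Fn1, at -3.45 ± 0.72. Summed stellate or fibroblast markers were 6.71 ± 1.37 CPM in Late and 70.04 ± 42.7 CPM in Ctrl. Among those that fell furthest were also the complement component C9 at -4.67 ± 1.17, ceruloplasmin, Cp, at -4.64 ± 0.80, the matrix Gla protein Mgp at -4.16 ± 0.78 and Pde4c at -4.73 ± 1.05. Others were Milr1 at -4.10 ± 0.78, Trim69 at -3.78 ± 0.89, Fgl2 at -3.70 ± 0.55 and Glis3 at -3.46 ± 0.63. Cp, Fgl2 and Glis3 are among the 10 top genes of the lymphatic-like cluster, which held 158 Ctrl and 0 Late cells.

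The hypoxia list had 1 gene up and 2 down of 13 (1 and 7 adjusted over the list alone, camera adjusted p = 0.00487, adjusted p = 0.376 with an estimated correlation), with the glycolytic enzyme Ldha at -0.81 ± 0.19 and the glucose transporter Slc2a1 at -1.43 ± 0.44. Adhesion molecules fell for 2 of 9 (2 adjusted over the list alone, camera adjusted p = 0.294), Sele at -1.47 ± 0.36 among them. Of 11 lipid genes 1 rose, Cd36 at 0.75 ± 0.15 (1 adjusted over the list alone, camera adjusted p = 0.394). Lpl had a log2 ratio of -3.28 ± 2.27 (edgeR adjusted p = 0.359) at 0.453 ± 0.524 CPM in Late. Tip cell genes had 1 up and 1 down of 16 (1 and 1 adjusted over the list alone, camera adjusted p = 0.148). Cell death genes had 1 up and 1 down of 14 (1 and 1 adjusted over the list alone, 0.625), vein genes 1 up of 8 (2 adjusted over the list alone, 0.16) and periportal or arterial genes 0 of 12 (0 adjusted over the list alone, 0.172). The count of 1424 genes fell to 285 without Late mouse 3, 598 without Late mouse 2, 822 without Ctrl mouse 1, 773 without Ctrl mouse 4 and 691 without Ctrl mouse 5.

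Late against Early asked which differences at 2 days were still present at 4 days. All 31 interferon-stimulated, 16 class I and 7 class II genes were lower in Late (adjusted p of 0.0229 to 0.031 with an estimated correlation), and 9 of 16 proliferation genes were higher (adjusted p = 0.111 with an estimated correlation). Cxcl9 stood at 113 ± 46.6 CPM in 4 Late mice and 2594 ± 1260 CPM in 6 Early mice (log2 ratio -4.50 ± 0.65, edgeR adjusted p = 0.000194), and Mki67 at 35.7 ± 15.2 and 4.62 ± 3.87 CPM (2.85 ± 0.40, edgeR adjusted p = 0.000151). In this contrast 384 genes rose and 677 fell.

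All 31 interferon-stimulated genes fell (median -2.77, adjusted p = 0.0229 with an estimated correlation), as did all 16 class I genes (-1.60, 0.0304) and all 7 class II genes (-4.44, 0.031), with the same counts adjusted over the list alone. Cd274 had a log2 ratio of -4.09 ± 0.54, Igtp of -4.60 ± 0.52, Gbp6 of -4.72 ± 0.51 and Tgtp1 of -5.30 ± 1.02. The ratio was also low for H2-Aa, at -5.37 ± 0.89, H2-Eb1, at -5.03 ± 0.92, and Ciita, at -5.82 ± 0.82. Ido1 had no UMI in Late, at least 50.02-fold lower than in Early by a floor of 3 counts over the group. Gbp10 had 1 UMI, a ratio of 227 with a counting interval from 40.5 to 8967. Chemokines fell for 3 of 5 (3 adjusted over the list alone, median -2.92, adjusted p = 0.0283 with an estimated correlation). Cell death genes fell for 6 of 14 (2 up and 6 down adjusted over the list alone, median -0.24, adjusted p = 0.0304 with an estimated correlation). Zbp1 had a log2 ratio of -3.97 ± 0.54.

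Proliferation genes rose for 9 of 16, 10 adjusted over the list alone (median 1.40, camera adjusted p = 1.03e-07, adjusted p = 0.111 with an estimated correlation). Hist1h2ap rose by 3.16 ± 0.70, Cenpf by 2.56 ± 0.43, the kinesin Kif23 by 2.49 ± 0.31, Hist1h2ae by 2.48 ± 0.68 and Prc1 by 2.35 ± 0.48. Tiam1 at 2.53 ± 0.28, Grik1 at 2.37 ± 0.25, Ces2e at 2.29 ± 0.32, Bc1 at 2.26 ± 0.33, Naaladl2 at 2.23 ± 0.29 and AC150683.1 at 2.99 ± 0.60 completed the genes that rose furthest. Immediate-early genes fell for 10 of 15, 12 adjusted over the list alone (median -1.07, adjusted p = 0.031 with an estimated correlation). Lymphatic genes fell for 4 of 5 (4 adjusted over the list alone, camera adjusted p = 0.00267, adjusted p = 0.0799 with an estimated correlation). Ccl21a had a log2 ratio of -7.69 ± 1.06 and Mmrn1 had a ratio of Early to Late of 52.5 (counting interval 17.9 to 256). Cp, a top gene of the lymphatic-like cluster (36 Early and 0 Late cells), had a log2 ratio of -5.02 ± 0.78. Periportal and arterial genes fell for 5 of 12 (5 adjusted over the list alone, camera adjusted p = 0.000383, adjusted p = 0.101 with an estimated correlation). Ly6a had a log2 ratio of -2.39 ± 0.23. Adhesion molecules fell for 2 of 9, 3 adjusted over the list alone (camera adjusted p = 0.0149, adjusted p = 0.101 with an estimated correlation). Vcam1 had a log2 ratio of -1.31 ± 0.20.

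The sinusoidal list (0 of 14, 0 adjusted over the list alone, camera adjusted p = 0.119), the Wnt2 and Rspo3 list (0 of 8, 0 adjusted over the list alone, 0.524), the vein list (0 of 8, 0 adjusted over the list alone, 0.994) and the lipid list (0 of 11, 0 adjusted over the list alone, 0.83) were not called between Late and Early. Nor were the tip cell list (1 down of 16, 1 adjusted over the list alone, 0.882), the matrix list (1 down of 10, 1 adjusted over the list alone, 0.882) and the hypoxia list (2 down of 13, 2 adjusted over the list alone, 0.0634). Lpl had a log2 ratio of -5.80 ± 1.89 (edgeR adjusted p = 0.0646). Leaving out Late mouse 3 lowered the count of 1061 genes to 664, and requiring at least 90% of hashtag counts from the cell's own tag lowered it to 585. The share of called genes that were higher was 36.2% with TMM factors and 54.7% with total UMIs alone.

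**Figure D2:**
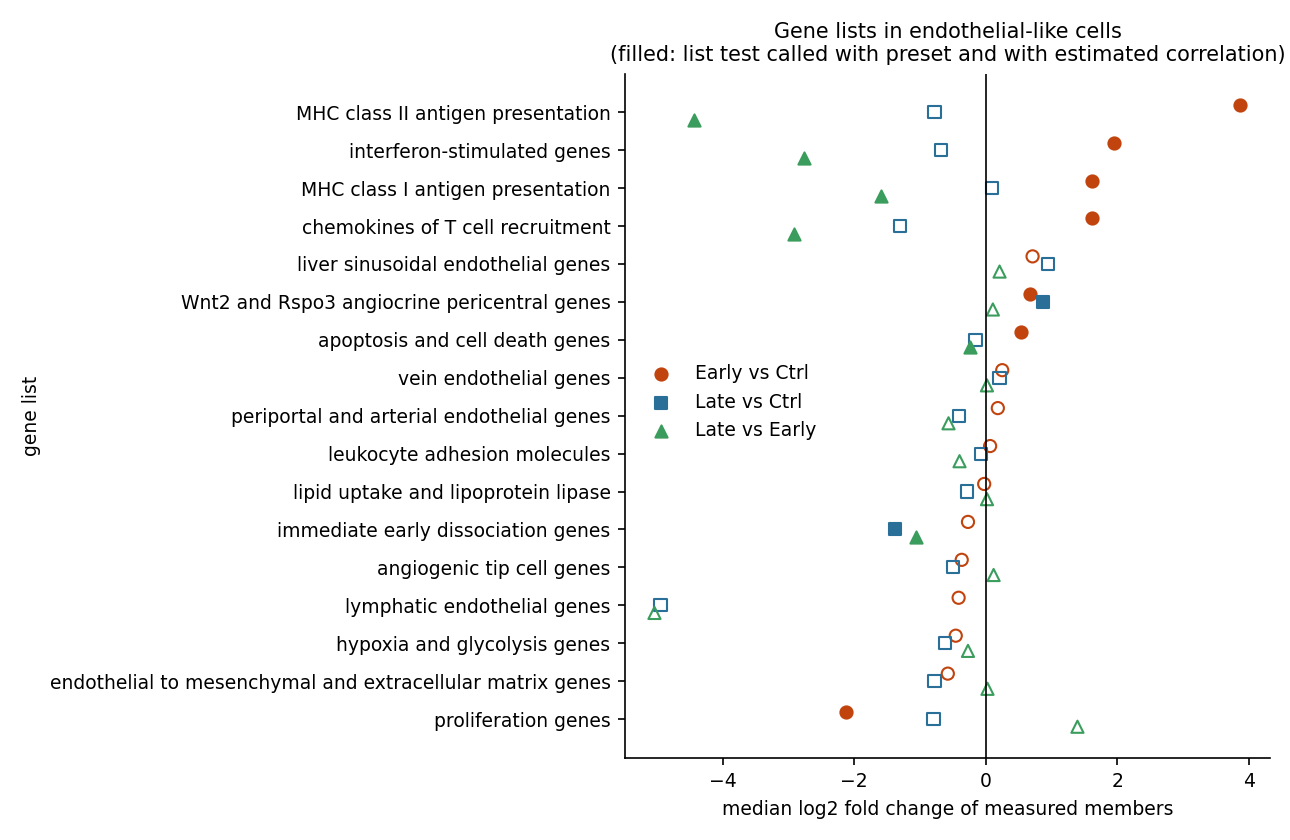
Median log2 ratio of the measured members of each gene list (x axis) in the 3 comparisons of endothelial-like cells, a marker per comparison, filled where the list test was called with both the preset and the estimated correlation. Class II genes sit at 3.88 in Early against Ctrl and at -4.44 in Late against Early.

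The endothelial classes were then examined each on its own, to ask whether differences held within vessel types. In sinusoidal-like cells 600 genes rose and 481 fell in Early against Ctrl, 222 and 221 in Late against Ctrl and 238 and 437 in Late against Early, of 7875 tested. H2-Aa stood at 51.4 ± 27.0 CPM in Early and 1.22 ± 0.872 CPM in Ctrl (log2 ratio 5.91 ± 0.39). H2-Eb1 rose too, at 5.88 ± 0.49, Cd74 at 5.83 ± 0.48, H2-Ab1 at 5.35 ± 0.47 and Ciita at 5.12 ± 0.52. Among the genes that fell furthest were Nav3 at -3.85 ± 0.66, Apln at -3.64 ± 0.52, the mechanosensitive channel Piezo2 at -3.46 ± 0.55 and Fbln2 at -3.46 ± 0.44. The class held a cluster of 977 cells with Abcc9, Kcnj8 and Ccl2 among its top genes. At resolution 1.6 a cluster of 443 cells with these top genes and Apln was named angiogenic-like. Nav3 and Piezo2 were top genes of the angiogenic-like cluster at 0.4. The falls of Nav3, Apln and Piezo2 in this class therefore need not lie in sinusoidal cells. All 5 measured class II genes rose (5 adjusted over the list alone, median 5.83), as did 16 of 16 class I genes (16 adjusted over the list alone) and 27 of 30 interferon-stimulated genes (29 adjusted over the list alone), each with adjusted p = 0.00179 with an estimated correlation. Late sinusoidal-like cells had more Grik1 (2.53 ± 0.35), Naaladl2 (2.28 ± 0.29), Lrp1b (2.16 ± 0.26), Sema3c (1.94 ± 0.17) and Camk1d (1.73 ± 0.20) than Ctrl. Hspa1a (-4.17 ± 0.68), Trim69 (-4.17 ± 0.91) and Apln (-3.88 ± 0.75) were lower. Ratios of Ctrl to Late were 33.9 for Milr1 (counting interval 9.34 to 281) and 28.2 for C9 (9.62 to 137). Against Early, Late cells had more Col18a1 (4.55 ± 1.05), Naaladl2 (2.84 ± 0.32), Grik1 (2.83 ± 0.39), AC150683.1 (2.61 ± 0.52) and Tiam1 (2.55 ± 0.42). They had less Gbp6 (-5.56 ± 0.51), Cd74 (-5.15 ± 0.65), Igtp (-4.86 ± 0.50) and Cxcl10 (-4.72 ± 0.40). Ciita had 1 UMI in Late, a ratio of Early to Late of 65.6 (counting interval 11.6 to 2602). Most Early cells of this class came from a cluster led by Calhm6, Cxcl9 and Cxcl10, with 785 Early, 44 Ctrl and 2 Late cells, so the class was filled by different clusters in each group. At resolution 0.4 the counts were 96, 282 and 84. The Late against Ctrl count of 443 was 240, 236, 242 and 98 without Ctrl mouse 3 or 5 or Late mouse 2 or 3, and 244 with the mouse number as a replicate block. The Late against Early count of 675 was 369, 396 and 445 without Early mouse 4 or Late mouse 3 or 4. With total UMIs in place of TMM the share higher went from 55.5% to 38.0% in Early against Ctrl and from 35.3% to 54.5% in Late against Early.

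Venous-like cells showed 606 genes up and 510 down in Early against Ctrl (5 mice each), 128 and 139 in Late against Ctrl, and 131 and 237 in Late against Early, of 7698. H2-Aa went from 17.96 ± 27.1 to 359 ± 79.3 CPM (4.99 ± 0.43). Gbp10 had a log2 ratio of 5.70 ± 0.56, H2-Eb1 of 5.17 ± 0.50, H2-Ab1 of 4.28 ± 0.42 and H2-DMb1 of 4.20 ± 0.53. Igfbp5 (-4.95 ± 0.78), Kif26b (-3.64 ± 0.77), the collagen receptor subunit Itga2 (-3.52 ± 0.39) and the apelin receptor Aplnr (-3.46 ± 0.63) fell. Class II genes rose for 7 of 7, class I for 16 of 16 and interferon-stimulated genes for 23 of 30 (7, 16 and 25 adjusted over the list alone, each adjusted p = 0.0281 with an estimated correlation). Late against Ctrl, Slco2b1 (2.20 ± 0.42), Rasa4 (2.10 ± 0.33), Sema3c (1.78 ± 0.18), Lfng (1.74 ± 0.34) and Lrp1b (1.69 ± 0.31) rose. D5Ertd615e (-4.18 ± 0.75) and Milr1 (no UMI in Late, at least 16.3-fold lower) fell. So did Pde4c, Trim69 and Cc2d2b, with ratios of Ctrl to Late of 69.8 (counting interval 12.4 to 2763), 57.3 (15.8 to 474) and 18.1 (4.96 to 151). In Late against Early, Aplnr (3.78 ± 0.71), Obsl1 (2.75 ± 0.56), Rapgef4 (2.13 ± 0.61), Lyve1 (2.11 ± 0.48) and Adamtsl1 (2.06 ± 0.32) rose. H2-Aa (-5.23 ± 0.61), Zbp1 (-4.90 ± 0.76), H2-Eb1 (-4.73 ± 0.64), Trim69 (ratio of Early to Late 56.4, counting interval 15.4 to 468) and Gbp10 (at least 15.8-fold lower) fell. A cluster with 256 Early, 4 Ctrl and 3 Late cells supplied most Early cells of this class. The Late against Ctrl count of 267 was 542, 137 and 136 without Ctrl mouse 2, 3 or 5 and 151, 95 and 171 without Late mouse 2, 3 or 4. The Early against Ctrl count of 1116 was 714 without Ctrl mouse 3.

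Arterial-like cells showed 371 genes up and 211 down in Early against Ctrl, 54 and 49 in Late (3 mice) against Ctrl, and 63 and 175 in Late against Early, of 7326. H2-Eb1 stood at 264 ± 79.7 CPM in Early and 1.07 ± 1.83 CPM in Ctrl (6.98 ± 0.36). Cd74 had a log2 ratio of 6.64 ± 0.49, H2-DMb1 of 6.22 ± 0.60 and H2-Aa of 6.03 ± 0.39, and Gbp10 was at least 133-fold higher over no UMI in Ctrl. Neurotensin, Nts (-4.96 ± 0.97), Trpm3 (-3.04 ± 0.56), the Wnt potentiator Rspo3 (-2.65 ± 0.52), Hmgb3 (-2.54 ± 0.52) and Cpe (-2.53 ± 0.66) fell. Class II genes rose for 7 of 7 and class I for 16 of 16 (7 and 16 adjusted over the list alone, adjusted p = 0.00141 with an estimated correlation), and interferon-stimulated genes for 29 of 31 (31 adjusted over the list alone, adjusted p = 0.0051 with an estimated correlation). Late against Ctrl, Fhdc1 (2.30 ± 0.46), Lrp1b (2.25 ± 0.38), Naaladl2 (2.16 ± 0.48), Sema3c (1.88 ± 0.20) and Cd84 (1.79 ± 0.31) rose. Cxcl9 (-4.29 ± 1.02), Mgp (-3.38 ± 0.84) and Cxcl10 (at least 29.5-fold lower) fell. So did Rsad2 and Myoz3, with ratios of Ctrl to Late of 12.5 (counting interval 4.25 to 60.8) and 27.8 (4.96 to 1100). From Early to Late, Lrp1b (2.98 ± 0.42), Stmn1 (2.28 ± 0.39), Naaladl2 (2.24 ± 0.50), Sema3c (2.06 ± 0.20) and Fzd8 (1.88 ± 0.45) rose. Cxcl9 (-6.99 ± 0.84), H2-Eb1 (ratio of Early to Late 134.5, counting interval 24.1 to 5319), Cxcl10 (at least 73.3-fold lower), Ciita (at least 13.3-fold) and H2-DMb1 (at least 8.71-fold) fell. A cluster with 295 Early, 18 Ctrl and 1 Late cells contributed to this class. The Late against Ctrl count of 103 was 161, 31, 62 and 39 without Ctrl mouse 2, 3, 4 or 5 and 14 and 29 without Late mouse 2 or 3. That of Early against Ctrl (582) was 307 and 375 without Ctrl mouse 3 or 5 and 333 with the replicate block, and that of Late against Early (238) was 153, 151 and 128 without Late mouse 2, 3 or 4. With total UMIs in place of TMM the share higher went from 63.8% to 51.7% in Early against Ctrl and from 26.5% to 41.0% in Late against Early.

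In angiogenic-like cells, 45 genes rose and 14 fell in 3 Early against 4 Ctrl mice, of 4425. The complement inhibitor Serping1 (4.15 ± 0.72), Cd274 (3.27 ± 0.66), H2-Q6 (2.94 ± 0.62), Sema3a (2.75 ± 0.52) and H2-Q7 (2.48 ± 0.46) rose. Hmcn1 (-2.28 ± 0.44), Sntb1 (-2.21 ± 0.34), Hotairm1 (-1.92 ± 0.39) and Chrm3 (at least 15.4-fold lower) fell. Differences between sinusoidal-like, venous-like and arterial-like cells in their list responses were tested directly with two-sided exact permutation tests. None of the 144 tests passed (0 called, 25 at an unadjusted p under 0.05), the smallest adjusted p being 0.184. The smallest p was 0.00794 with 5 against 5 mice and 0.0179 with 3 against 5, the lowest such tests can give, so the design limits the calls. Gene by gene, limma on differences between classes within each mouse called 3, 0 and 3 genes for sinusoidal-like against venous-like cells (of 7147, in Early against Ctrl, Late against Ctrl and Late against Early, with 478, 741 and 816 at an unadjusted p under 0.05). It called 0, 0 and 0 for sinusoidal-like against arterial-like (of 6891, with 330, 592 and 768 at an unadjusted p under 0.05) and 0, 2 and 1 for venous-like against arterial-like cells (of 6934, with 507, 858 and 848).

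Shares of the classes were taken from clusters rebuilt without the genes called in any comparison. One rebuilt cluster of 715 cells, with Sparcl1, Rgcc, Car4 and Lpl among its top genes, scored best for the stellate or fibroblast list (1.44). By the naming rule it was left out of the total, as were the immune-like, erythroid-like and melanocytic-like clusters. The endothelial-like cells of these shares are therefore not the same set as in the expression tests. At resolution 0.4 of the first clustering, a cluster of 861 cells with Sparcl1, Rgcc and Lpl among its top genes was named arterial-like. The arterial-like shares given here may thus depend on how such cells are named. Arterial-like cells made up 20.8 ± 4.83% of endothelial-like cells in 6 Early mice and 7.01 ± 2.94% in 4 Late mice (two-sided exact permutation test, p = 0.00476, the smallest the design allows, adjusted p = 0.0238 over 10 shares). The arterial-like share was 12.4 ± 4.57% in Ctrl (Early against Ctrl exact p = 0.0195, adjusted p = 0.0974). Sinusoidal-like cells made up 24.2 ± 11.8% in Ctrl, 31.0 ± 11.2% in Early and 35.2 ± 6.86% in Late. At resolution 0.4 of the first clustering, Early minus Ctrl was -24.1 points (adjusted p = 0.0108), with 107 Early cells in the class. There a cluster of 871 Early and 45 Ctrl cells, with its best score for the sinusoidal list, stayed unnamed because C1qb was among its top genes. Venous-like cells made up 22.04 ± 16.3%, 22.2 ± 7.71% and 26.3 ± 7.90%. Angiogenic-like cells made up 11.4 ± 9.12%, 3.79 ± 2.25% and 4.59 ± 4.75%. Lymphatic-like cells made up 3.41 ± 1.79% in Ctrl and 1.78 ± 1.49% in Early, with 0 of 690 cells in Late, which allows up to 0.435% (Late against Ctrl exact p = 0.0159, adjusted p = 0.119). Of the unnamed rebuilt clusters, that led by Hist1h2ap, Hist1h2ae and Neil3 made up 1.92 ± 0.732% in Ctrl and 0.0781 ± 0.121% in Early (adjusted p = 0.0217). A further one, led by Birc5, Ube2c and Cks1b, made up 10.9 ± 2.65% in Late and 4.21 ± 1.61% in Early (adjusted p = 0.0238). It held 418 cells, and the cluster led by Hist1h2ap 112. The Ctrl share of the larger cluster is not reported here. A fall from Ctrl to Early is therefore given for the smaller cluster alone. The arterial-like call between Late and Early was lost without Late mouse 1, 3 or 4 (0 classes passed, adjusted p = 0.0595 each), where 3 mice leave the exact test little room. The differences there were -12.45, -13.7 and -14.2 points, against -13.8 with all mice. Between Early and Ctrl, angiogenic-like cells passed without Ctrl mouse 2 (-10.2 points, exact permutation test, adjusted p = 0.032). Arterial-like cells passed without Ctrl mouse 5 (10.4 points, 0.048). The arterial-like difference also passed in the first clustering, which used the called genes (9.6 points, 0.029), with its other cell filters or doublets kept, and at its resolution 1.6 (11.4 points, 0.022).

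**Figure D3:**
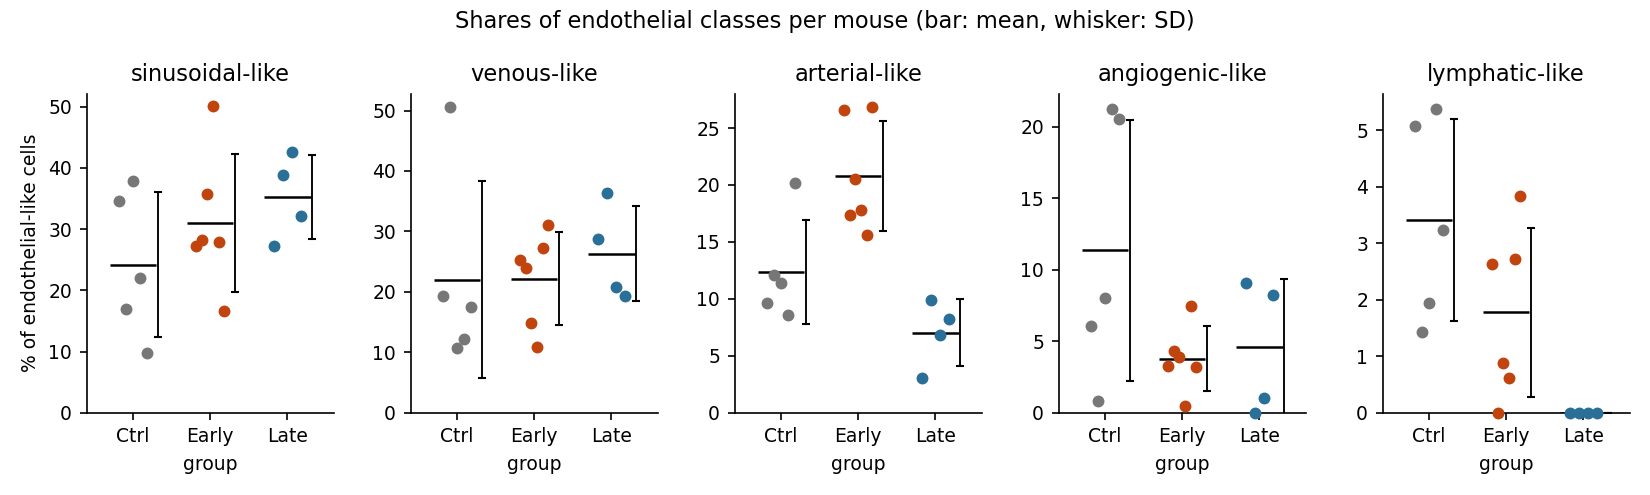
Share of each endothelial class among endothelial-like cells of the rebuilt clusters (%, y axis), 1 point per mouse in Ctrl (5), Early (6) and Late (4), with the mean as a bar and the SD as a whisker. The total leaves out the rebuilt cluster of 715 cells that scored best for the stellate or fibroblast list. Arterial-like shares are 20.8% on average in Early and 7.01% in Late.

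The immune comparison asked what endothelial loss of Lpl changed in immune cells of the metastases 2 days after T cell transfer. Clusters 12 and 17 carried Cd3e (552 and 356 CPM) and Cd8a (443 and 317 CPM), with Pdcd1, Tox and Cxcr6 leading the former and Ifng, Gzmb and Xcl1 the latter, and are called T cell clusters here. In them 16 genes were higher and 131 lower in 6 iECKO than in 6 WT mice, of 11239 tested with edgeR. Clusters 12 and 17 were summed as 1 class per mouse, so a shift between them can enter these differences. Gzma, which encodes a cytotoxic granule protease, stood at 858 ± 41.4 CPM in iECKO and 520 ± 142 CPM in WT (log2 ratio 0.72 ± 0.13, edgeR adjusted p = 0.00833), with each iECKO mouse above each WT mouse. Lars2, a mitochondrial leucyl-tRNA synthetase, stood at 80.1 ± 10.2 and 216 ± 20.6 CPM (-1.45 ± 0.09, edgeR adjusted p = 5.94e-08), and the noncoding AY036118 (ENSMUSG00000105361, mm10 chromosome 17, 39847113 to 39848035) at 28.3 ± 6.80 and 101 ± 14.8 CPM (-1.90 ± 0.14). Gm42418 had a log2 ratio of -0.98 ± 0.14 in them, mt-Atp8 of -0.92 ± 0.07, Rps27 of -0.30 ± 0.05 and Gm10076 of 0.79 ± 0.06. The falls of Lars2 and AY036118 were not particular to T cells: they were called in 11 and 13 of the 15 immune classes tested.

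Besides Gzma, the genes that rose furthest in the T cell clusters were Banp at 0.44 ± 0.09, the proteasome activator subunit Psme2b at 0.40 ± 0.09 and Trim8 at 0.37 ± 0.09. They were followed by the Notch modifier Lfng at 0.36 ± 0.07, Jund at 0.33 ± 0.05, Setd1b at 0.31 ± 0.06, Alyref at 0.30 ± 0.07, H2-T23 at 0.29 ± 0.07, Ccdc115 at 0.29 ± 0.07, Gnb2 at 0.25 ± 0.05 and Ubn2 at 0.22 ± 0.05. Among those that fell furthest were Hist1h3e at -1.65 ± 0.14, Hist1h2an at -1.50 ± 0.22, Hist1h4h at -1.50 ± 0.19 and Hist1h3f at -1.48 ± 0.16. Hist1h3c stood at -1.39 ± 0.14, Hist1h2ab at -1.36 ± 0.14 and Hist1h4d at -1.36 ± 0.13. Insyn2b at -1.65 ± 0.19, Il31ra at -1.58 ± 0.10 and Lrrc4 at -1.41 ± 0.10 fell too. In the effector list 1 of 14 genes rose, Gzma (1 adjusted over the list alone, median 0.26, camera adjusted p = 0.00424, adjusted p = 0.128 with an estimated correlation). Ifng had a log2 ratio of 0.62 (edgeR adjusted p = 0.561), Gzmb of 0.21 (0.674) and Ccl5 of 0.39 (0.752). No gene passed in the inhibitory receptor list (0 of 12, 0 adjusted over the list alone, camera adjusted p = 0.383), with Pdcd1 at 0.07, nor in the naive and memory list (0 of 9, 0 adjusted over the list alone, 0.132), with Tcf7 at -0.37, nor in the fatty acid oxidation list (0 of 12, 0 adjusted over the list alone, 0.632).

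With doublets kept, the medians of the class II, chemokine and interferon lists in the T cell clusters were 0.26, 0.16 and 0.0301. Class II genes were lower in these clusters for 2 of 7, 5 adjusted over the list alone (median -0.54, camera adjusted p = 0.000131, adjusted p = 0.187 with an estimated correlation), and chemokines for 2 of 4 (2 adjusted over the list alone, median -0.56, camera adjusted p = 0.000748, adjusted p = 0.0868 with an estimated correlation). Inflammatory macrophage genes were lower for 0 of 10, 7 adjusted over the list alone (median -0.57, camera adjusted p = 0.000243, adjusted p = 0.0868 with an estimated correlation). These lists hold mainly genes of myeloid cells, though Ccl5 and Tnf are on the T cell effector list as well. Summed endothelial markers in the same clusters were 75.2 CPM in iECKO and 89.0 CPM in WT, and epithelial markers 65.3 and 45.7 CPM. Interferon-stimulated genes had a median of -0.09 (0 of 30, 1 down adjusted over the list alone, camera adjusted p = 0.0221, adjusted p = 0.738 with an estimated correlation) and lipid genes of -0.21 (0 of 6, 1 down adjusted over the list alone, camera adjusted p = 0.00951, adjusted p = 0.0868 with an estimated correlation). The class I (1 up of 16, camera adjusted p = 0.192), proliferation (0 of 16, 0.0921) and immediate-early (1 up of 15, 0.632) lists were not called. Neither were the hypoxia (0 of 13, 0.622), cell death (0 of 15, 0.632), lipid associated macrophage (0 of 9, 0.632), immunoregulatory macrophage (0 of 8, 0.247) and dendritic cell maturation (0 of 8, 0.065) lists. Adjusted over the list alone, 1 class I gene and 1 immediate-early gene rose, 3 proliferation genes fell and the others had 0. The histone genes named above as lower are not on the proliferation list, so their fall comes without a call of that list. In the sum of the other immune cells of the same mice, the 131 lower genes had a median log2 ratio of -0.91, against -1.12 in the T cell clusters. After subtracting those cells, limma called 1 gene, 1600010M07Rik (-0.87). Of the higher genes, Gzma included, 0 stayed past the threshold. Whether the rise of Gzma is particular to the T cell clusters is therefore not settled. A cell's own hashtag was its highest in 91.8% of iECKO cells and 99.7% of WT cells, with 78.8% in iECKO mouse 1, 80.9% in iECKO mouse 6 and 96.6% to 100% in the other iECKO mice. Without iECKO mice 1 and 6 the count of 147 genes was 119, and Alyref, Ccdc115, Gnb2, H2-T23, Lfng, Psme2b, Setd1b and Trim8 did not pass (edgeR adjusted p from 0.0503 to 0.139), with log2 ratios from 0.26 to 0.40. In that fit the naive and memory list (median -0.42, camera adjusted p = 0.0161) and the class I list (0.10, 0.00334) passed with the preset correlation, and the interferon (-0.04, 0.469) and lipid lists (-0.21, 0.129) did not.

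Macrophage-like cells had 3 genes higher and 25 lower of 9318. Arg1, Flrt2, Gpnmb and Thbs1 were among the top genes of this class. At resolution 1.6 a cluster of 943 cells with these top genes was named monocyte-like, so the monocyte content of the class is not settled. F13a1, coagulation factor XIII A and a member of the monocyte marker list, stood at 1072 ± 165 CPM in iECKO and 650 ± 142 CPM in WT (0.72 ± 0.13, edgeR adjusted p = 0.0251). Ppp1r3b, a glycogen-targeting phosphatase subunit, rose by 0.53 ± 0.10. Without iECKO mice 1 and 6 neither passed, with log2 ratios of 0.77 and 0.50 (edgeR adjusted p = 0.0591 and 0.121), and Ppp1r3b had a log2 ratio of -0.26 at resolution 1.6. Cmss1 (ENSMUSG00000022748, mm10 chromosome 16, 57302000 to 57606864) stood at 197 ± 25.9 and 547 ± 62.7 CPM (-1.47 ± 0.10). Ankdd1a had a log2 ratio of -1.76 ± 0.22, AY036118 of -1.47 ± 0.17, Lars2 of -1.29 ± 0.12 and Il31ra of -1.26 ± 0.15. Lpl had a log2 ratio of -0.22 (edgeR adjusted p = 0.808) at 188 ± 62.5 and 219 ± 56.6 CPM, which checks nothing about the endothelial deletion. Class I (median -0.09), immediate-early (0.15), hypoxia (0.09) and effector genes (-0.46) passed camera with the preset correlation at adjusted p of 0.0283, 0.0283, 0.00904 and 0.00854. With an estimated correlation their adjusted p were 0.729, 0.729, 0.729 and 0.0801. None of their genes passed over all genes, and 4 hypoxia genes did adjusted over the list alone. The hypoxia median was -0.0046 at resolution 1.6 and the class I median 0.0057 at 0.4. Without iECKO mice 1 and 6 the immediate-early list was not called (median 0.13, camera adjusted p = 0.142), and the chemokine (-0.32, 0.0446) and interferon lists (-0.07, 0.00781) were, with the preset correlation. The inflammatory (0 of 11), immunoregulatory (0 of 10), lipid associated (0 of 12) and class II (0 of 7) lists were not called, with camera adjusted p of 0.758, 0.305, 0.758 and 0.759 and 0 genes adjusted over the list alone. The count of 28 genes was 15 without iECKO mouse 5, 17 without iECKO mouse 1 and 18 without iECKO mice 1 and 6. It was 75 with DESeq2, 10 with limma on the mean of per-cell CPM and 0 with edgeR (550 genes at an unadjusted p under 0.05) where at least 90% of a cell's hashtag counts had to come from its own tag. With DESeq2 the share higher was 30.7%, against 10.7%.

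In monocyte-like cells 19 genes rose and 91 fell of 9906. The glucocorticoid-induced Tsc22d3 stood at 70.7 ± 16.2 CPM in iECKO and 37.8 ± 10.7 CPM in WT (0.90 ± 0.17, edgeR adjusted p = 0.0130). Kbtbd11 (0.78 ± 0.16), Ankrd28 (0.70 ± 0.15), the cyclin Ccnd3 (0.66 ± 0.11) and the quiescence factor Klf2 (0.51 ± 0.11) rose. Without iECKO mice 1 and 6 the log2 ratio was 0.88 for Tsc22d3 (adjusted p = 0.0568), 0.66 for Kbtbd11 (0.119) and 0.54 for Klf2 (0.0539). Cmss1 stood at 140 ± 16.6 and 458 ± 35.2 CPM (-1.71 ± 0.08, edgeR adjusted p = 9.31e-10). Tldc2 had a log2 ratio of -2.04 ± 0.22, AY036118 of -1.88 ± 0.12, Il31ra of -1.49 ± 0.11 and Ccdc162 of -1.37 ± 0.25. Inflammatory macrophage genes had 0 of 10 lower, 4 adjusted over the list alone (camera adjusted p = 0.000521, adjusted p = 0.257 with an estimated correlation). Effector genes had 1 of 11 lower, 4 adjusted over the list alone (0.000521, adjusted p = 0.257 with an estimated correlation), and immunoregulatory genes 0 of 10, 3 adjusted over the list alone (0.00954, adjusted p = 0.355 with an estimated correlation). Interferon-stimulated genes had 1 of 31 lower, 2 adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.571 with an estimated correlation). Cell death genes had 0 of 14 lower, 2 adjusted over the list alone (0.00885, adjusted p = 0.355 with an estimated correlation), and class II genes 0 of 7 with a median of 0.11 (0 adjusted over the list alone, 0.0489, adjusted p = 0.571 with an estimated correlation). Without iECKO mice 1 and 6 the class II list was not called (median 0.044, camera adjusted p = 0.541), and with at least 70% of hashtag counts from the own tag the interferon median was 0.0094. The count of 110 genes was 176 with DESeq2, 66 with at least 70% of hashtag counts from the own tag, 68 with the mouse number as a replicate block and 70 at resolution 0.4.

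Across the 15 immune classes tested, Cmss1 was lower in iECKO in 14, AY036118 in 13, Cdk8 in 12 and Lars2 in 11. The gene model Gm42418 was lower in 9, the mitochondrial mt-Atp8 in 9 of 14 and the ribosomal protein gene Rps27 in 5. Gm10076 was higher in 9 and mt-Co1 in 3. Tsc22d3 was higher in 5 of 13 and Ccnd3 in 4 of 15 classes. In non-classical monocyte-like cells (13 up, 26 down) Tsc22d3 rose by 1.30 ± 0.13, Ccnd3 by 1.18 ± 0.14 and the chemokine receptor Cxcr4 by 0.67 ± 0.11, while the monocyte attractant Ccl7 had a log2 ratio of -2.19 ± 0.39. B-like cells (6 up, 13 down) had Tsc22d3 at 0.85 ± 0.12, Cxcr4 at 0.76 ± 0.14 and Cxcl9 at -1.84 ± 0.30. Neutrophil-like cells (7 up, 12 down) had Syne1 at 1.202 ± 0.24 and Tsc22d3 at 0.98 ± 0.22, and NK-like cells (1 up, 7 down) Cxcl9 at -1.73 ± 0.34. Cxcl9 was a top gene of a macrophage-like cluster in the iECKI matrix and of no B-like or NK-like cluster. Free RNA from other cells was not tested for its fall in B-like and NK-like cells. Mature dendritic-like cells had 0 genes past the edgeR threshold in 4 against 4 mice, with 145 at an unadjusted p under 0.05, and DESeq2 called 2 and limma 0. Of the shares of 18 immune classes and clusters, rebuilt without the called genes, no named class passed the threshold (two-sided exact permutation tests). The counterparts of T cell clusters 12 and 17 made up 5.89 ± 4.59% and 6.14 ± 3.04% in iECKO against 4.10 ± 2.26% and 6.05 ± 1.82% in WT. Macrophage-like cells made up 7.58 ± 1.84% against 8.70 ± 2.72% and monocyte-like cells 20.8 ± 5.11% against 18.9 ± 3.59%. These 2 names cover partly other cells than in the expression tests. The rebuilt cluster of 894 cells led by Arg1, Thbs1 and Flrt2, top genes of the macrophage-like cells tested, was named monocyte-like. An unnamed cluster of low-UMI cells made up 1.13 ± 0.573% in iECKO and 4.62 ± 1.10% in WT (exact p = 0.00217, adjusted p = 0.0390).

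**Figure D4:**
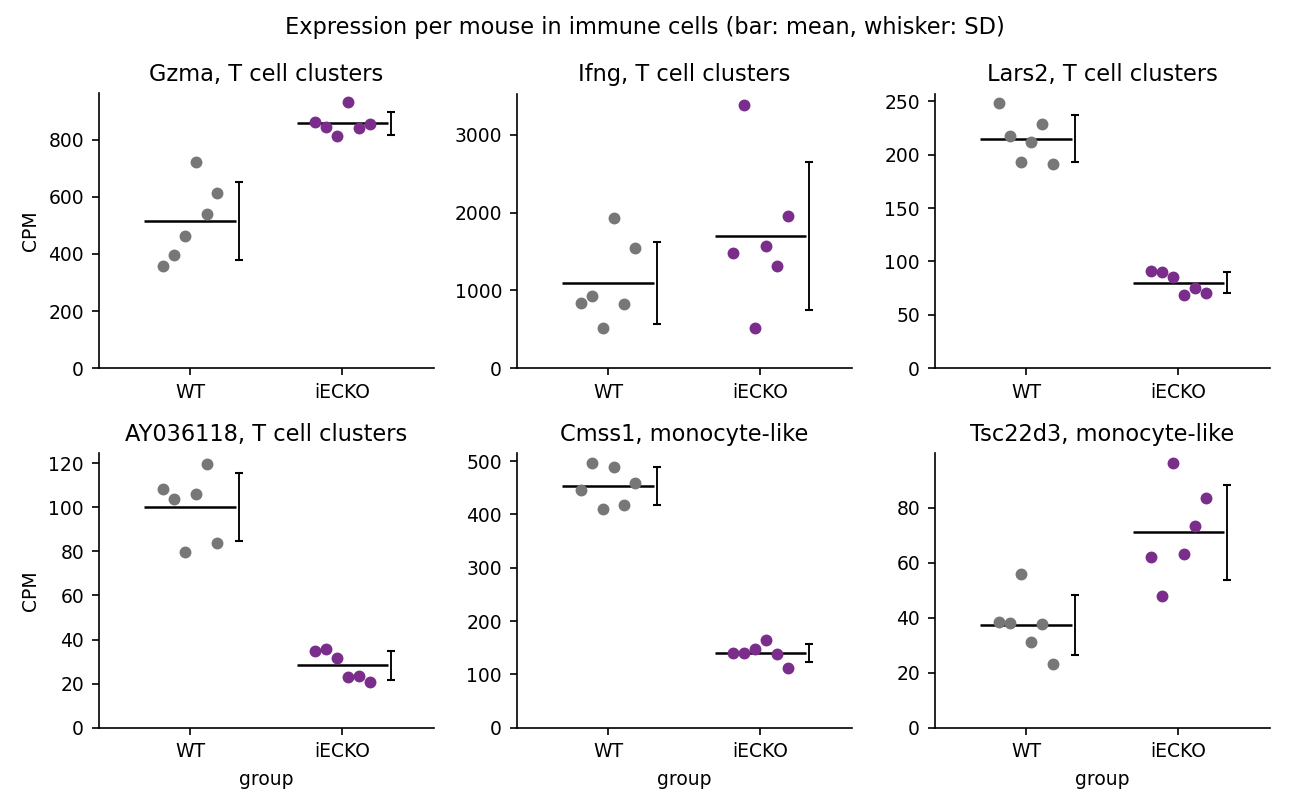
CPM (y axis from 0, not TMM-scaled) of 6 gene and class pairs, 1 point per mouse (6 WT, 6 iECKO), with the mean as a bar and the SD as a whisker. Lars2, AY036118 and Cmss1 are lower in each iECKO mouse than in each WT mouse, Gzma is higher in each, and Ifng and Tsc22d3 overlap.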

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

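Tests of the lower genes in T cell clusters 12 and 17 against the other immune cells, of subtype shifts behind the class II genes, of a library-wide difference in Late and all splits of the mice were chosen only after the result was seen.

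Of 255 groups of mice tested, 17 had a mouse far from the others, against 12.8 expected, since chance flags about 1 in 20 groups. Early mouse 2, the mouse with the fewest cells, was low for Ccl21a (1.74 log2 CPM, the others 6.40 to 7.94) and Mmrn1 (-1.36, which is 0 UMIs, others 4.22 to 5.37). It also had 0 UMIs of Tiam1 (-1.36, others 1.34 to 2.29 with 4 to 18 UMIs), too few to show a low level. Early mouse 3 was low for Cenpf (0.54, others 2.10 to 2.85). Ctrl mouse 2 was high for Pde4c (5.67, others 4.64 to 4.92) and Wnt2 (7.58, others 5.71 to 6.02), low for Tiam1 (2.12, others 2.92 to 3.11) and had a venous-like share of 50.6% (others 10.7% to 19.3%). Ctrl mouse 1 was high for Mmrn1 (6.00, others 5.14 to 5.33). In Late, mouse 4 had 1 UMI of Gbp10 (0.40) and the others 0 (-1.36), and mouse 2 had 0 UMIs of H2-DMb1 (-1.36, others 0.92 to 1.29 with 1 to 7 UMIs), too few to show a difference in level. Late mouse 1 had a median of 7890 UMIs per cell (others 6822 to 6966). In iECKO, mouse 3 was low for Alyref (7.86, others 7.98 to 8.04), mouse 2 high for Lrrc4 (3.96, others 3.42 to 3.56), and mouse 1 had a B-like share of 11.01% (others 4.03% to 6.49%). In WT, mouse 6 was high for Lrrc4 (5.19, others 4.83 to 4.93) and mouse 1 for Ubn2 (7.27, others 7.12 to 7.17).

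The iECKI matrix, whose 10 mice in 2 hashtag sets may mix LSL-WT and knock-in and entered no comparison, held signal for each gene looked at, as medians over 10 mice with their range. Lpl stood at 148 CPM (56.7 to 214), Cxcl9 at 778 (426 to 1461), Cd8a at 33.8 (21.8 to 89.6), Gzmb at 392 (177 to 484), Ifng at 205 (157 to 338), Foxp3 at 2.40 (0.697 to 4.27), Lyz2 at 5027 (2913 to 6189), Tsc22d3 at 63.1 (42.7 to 135), Cmss1 at 5097 (4244 to 5870), AY036118 at 2859 (2578 to 3004), Lars2 at 3027 (2593 to 3613) and H2-Aa at 2150 (1552 to 2809).

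The 131 genes lower in the T cell clusters of iECKO mice had a median log2 ratio of -1.12 there and of -0.91 in the sum of the other immune classes of the same mice, where 127 of 131 were lower and 75 passed the threshold. After subtracting those classes 0.763% of them stayed past the threshold, with a limma median of -0.25 and a median SE of 0.222, against -1.07 and 0.167 before, so a difference of full size specific to these clusters is argued against for the set. A smaller one stays open, since 99 of the 131 genes still lay below 0. The same question was asked first of B-like cells, where 46 of the genes were measured and 39 were lower, with a median of -0.44 against -0.72 in the T cell clusters. A library-wide difference, which genotype and library share in this design, is a candidate explanation. Free RNA from other cells stays open, since 30.5% of the genes had a higher mean in the other classes of WT.

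The rise of class II genes in Early endothelial cells was set against immune RNA, depth and subtype. The median rise of 20 abundant immune genes was 0.000903 of that which immune RNA would need, and Ctss, the highest, reached 0.0685, which argues against RNA from immune cells. With each mouse thinned to 340071 UMIs the median was 3.74, against 3.88, which argues against depth. Within sinusoidal-like, venous-like and arterial-like cells the lowest median was 4.20, which speaks only to shifts between these classes. Most Early sinusoidal-like and venous-like cells came from clusters with few Ctrl cells. H2-Eb1, H2-Aa and H2-Ab1 were top genes of that venous-like cluster, so the clustering used the genes tested. A shift between clusters inside a class stays open. Library and group cannot be told apart here, and a response to the transferred T cells may underlie the rise as a hypothesis not tested here.

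The genes higher in Late than in Ctrl had a median of 0.67, and the longest 10% of all genes exceeded the shortest 10% by 0.28, against 0.37 in Early against Ctrl. A gene length effect stays open, as does a library-wide difference: the lowest median of these genes within sinusoidal-like, venous-like and arterial-like cells was 0.50. No biological explanation was tested.

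Under 5% of the splits of the mice, the real one included, gave as many genes for each count followed, which argues against chance. It does not exclude chance, since at most 100 splits were run per count and the counts were chosen after they were seen. In all endothelial-like cells the real count was 2187 and the highest of the other splits 1543 for Early against Ctrl, 1424 and 529 for Late against Ctrl, and 1061 and 58 for Late against Early. In the same order the real and highest other counts were 1081 and 1049, 443 and 92, and 675 and 223 in sinusoidal-like cells, 1116 and 326, 267 and 445, and 368 and 108 in venous-like cells, and 582 and 514, 103 and 24, and 238 and 31 in arterial-like cells. For venous-like cells in Late against Ctrl, 1 of the 99 other splits gave more genes than the real one. No other split reached the real count elsewhere. In immune cells the counts were 147 and 3 in the T cell clusters, 28 and 2 in macrophage-like, 110 and 2 in monocyte-like cells and 94 and 8 in the 7 other named immune classes.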

How the results depend on the processing

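Total UMIs without TMM factors, only the 2 groups compared in the fit, subtraction of other immune cells, iECKO mice 1 and 6 left out together and the rebuilt clusters were chosen after seeing the data. Leaving out wells, a pseudocount of 10 and thinned cells were not run. Of 2064 gene ratios in endothelial cells over settings other than leaving out a mouse, 1983 kept direction and side of the threshold and 0 reversed, and of 524 in immune cells 452 and 1. The cause of the changes below was not tested.

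Counts moved by over 1.5 times as follows. With limma on the mean of per-cell CPM, the counts were 954 (main 2187) in all endothelial-like cells for Early against Ctrl, 278 and 164 (1081, 443) in sinusoidal-like cells for Early and Late against Ctrl, 479 and 118 (1116, 267) in venous-like, 111 and 44 (582, 103) in arterial-like, 86 (147) in the T cell clusters and 10 (28) in macrophage-like cells. With at least 90% of hashtag counts from the own tag they were 585 (1061) in all endothelial-like cells and 399 (675) in sinusoidal-like cells for Late against Early, 495, 58 and 108 in venous-like and 342, 34 and 86 in arterial-like cells over the 3 comparisons, and 0 in macrophage-like cells with edgeR (550 at an unadjusted p under 0.05), against 75 with DESeq2 on all cells. With 70% they were 18 in macrophage-like and 66 (110) in monocyte-like cells. With the mouse number as a replicate block they were 333 in arterial-like cells for Early, 244 in sinusoidal-like cells for Late against Ctrl and 68 in monocyte-like cells. DESeq2 gave 175 in arterial-like cells for Late against Ctrl, 75 in macrophage-like and 176 in monocyte-like cells. Resolution 0.4 gave 96, 282 and 84 in sinusoidal-like cells, 465 in arterial-like and 538 in venous-like cells for Late against Ctrl, 116 in macrophage-like and 70 in monocyte-like cells. Resolution 1.6 gave 563 in sinusoidal-like cells for Early, 474 in venous-like cells for Late against Ctrl, 14 in macrophage-like cells and 145 (94) in the 7 other immune classes. Without iECKO mice 1 and 6 the count was 18 in macrophage-like cells. After subtracting other immune classes 1 gene was left in the T cell clusters.

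Classes with a share past the threshold went from 0 to 1 for Early against Ctrl with clusters from all variable genes, doublets kept, no cell filter, the stricter filter or resolution 0.4, and to 2 at 1.6. For Late against Ctrl they went from 0 to 1 with no filter, the stricter filter or either resolution, and for Late against Early from 1 to 2 at 0.4. For immune cells they went from 0 to 1 at 0.4, with Kupffer-like cells (-3.66 points in iECKO, exact permutation test, adjusted p = 0.0217). That class held 533 cells at 0.4 and 82 at 0.8.

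Lowest and highest counts with 1 mouse left out were, for Early against Ctrl, Late against Ctrl and Late against Early, 1403 to 2612, 285 to 1774 and 664 to 1176 in all endothelial-like cells, 728 to 1198, 98 to 552 and 369 to 768 in sinusoidal-like, 714 to 1368, 95 to 542 and 271 to 381 in venous-like, 307 to 601, 14 to 161 and 128 to 284 in arterial-like cells, and 0 to 1, 0 to 0 and 0 to 1 for shares. They were 104 to 144 in the T cell clusters, 15 to 37 in macrophage-like and 81 to 164 in monocyte-like cells.

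Reversed in sinusoidal-like cells were the medians of periportal genes in Early against Ctrl without Ctrl mouse 2 (0.16, the lowest being -0.0524 without Ctrl mouse 1), proliferation genes in Late against Ctrl with no filter on low counts (-0.38), and hypoxia genes in Late against Early at resolution 0.4 (0.0075) and without Late mouse 2 (0.0035, the lowest being -0.44 without Late mouse 3). So was the sinusoidal-like share in Early against Ctrl at 0.4 (-24.1 points), where a cluster of 871 Early cells with its best score for the sinusoidal list stayed unnamed. With doublets kept, class II, chemokine and interferon medians in the T cell clusters were 0.26, 0.16 and 0.0301. In macrophage-like cells Ppp1r3b was -0.26 and the hypoxia median -0.0046 at 1.6, the class I median 0.0057 at 0.4 and the class II median -0.32 at 90% of hashtag counts. In monocyte-like cells the interferon median was 0.0094 at 70%.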

Other observations

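No test in this part was planned: the values were chosen only after the results were seen. Cluster 3 of the endothelial cells, led by Tafa2, Plppr5, Tenm1, C1qb and Wnt2, scored highest for the sinusoidal list (0.591, 6 markers higher) and stayed unnamed because C1qb is a macrophage marker. It had 160 genes higher and 78 lower in Early than in Ctrl, of 4382 tested with edgeR. Cxcl9 rose by 3.73 ± 0.41 on the log2 scale and Cd274 by 3.73 ± 0.34, and H2-Aa had 1 UMI in Ctrl, a ratio of Early to Ctrl of 365.5 with a counting interval from 64.1 to 14580.0. Late against Ctrl, 143 genes rose and 247 fell, with Sema3c at 1.86 ± 0.26 and the metalloprotease Adamts9 at -2.01 ± 0.25. Lpl was among the genes leading a further unnamed endothelial cluster with Car4 and Rgcc.

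Over the 10 mice of the iECKI matrix, whose genotypes are not given in the sources used here, B-like cells had a median share of 10.5% (4.96% to 44.1%), neutrophil-like cells of 15.6% (3.86% to 29.7%), macrophage-like cells of 8.65% (4.01% to 17.6%) and CD8 T-like cells of 2.34% (1.29% to 5.26%).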
